A study of Homo sapiens with 5 samples.

How the data were processed

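Ribosome profiling libraries were analysed from 5 samples of HEK293T cells, grouped by the genotype in the labels into QTRT1 knockout (1 library), QTGAL knockout (2 libraries) and QTMAN knockout (2 libraries). Per the labels' protocols, extracts were treated with RNase I, ribosomes were pelleted, short fragments were cut from a gel, a linker was ligated, ribosomal RNA was depleted, and cDNA was circularised and amplified. No molecular identifiers are mentioned, so counting precision covers reads and not molecules. The titles carry 2 numbers after the gene name whose meaning the labels do not give, and replicates were numbered here in accession order. Nothing in the labels places the 2 libraries of a genotype in separate cultures or clones, so p-values measure the spread between these libraries, which may be technical.

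The deposited files hold 1 table per library with an identifier, a length and a whole-number count of footprints per transcript, not normalized. The submitters' processing notes name bcl2fastq 2.19, CASAVA and STAR 2.7.0a, and the genome build hg38. The annotation, the counting program, the strand setting and the footprint lengths counted are not given in the sources used here. All 5 tables list the same 182398 identifiers in the same order. A length is given for 93916, and the 88482 transcripts without one have a count of 0 in every library, so only transcripts with a length were tested. The deposited length column, of unit other than a count, runs from 1 to 35992 with a median of 227, and 33.1% of its values are multiples of 3, so it is not a nucleotide length of complete reading frames and was read as codons. Of the 79348 transcripts with a count, 59099 have distinct counts over the 5 libraries, and 8561 pairs of adjacent rows have the same counts, as isoforms that share footprints would; low counts can also coincide by chance. Calls on neighbouring rows are therefore not taken as independent, and paralogs or overlapping genes may share footprints as well.

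The tables do not pair the identifiers with genes, and the reference table given holds no such identifiers for protein-coding genes. The gene lists, the check of the knocked-out genes and the relation to codon content that had been planned could not be run, and neither could the alternatives that need gene names or biotypes (protein-coding genes only, and leaving out mitochondrial and histone genes). No genome was used, so no coordinates are given and a position is a row number in the tables.

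The main test was edgeR 4.0.16 in R 4.3.3 on the counts: filterByExpr by genotype (60966 transcripts kept), TMM factors (0.967 to 1.02), and the quasi-likelihood test (glmQLFit and glmQLFTest) in a model with 1 mean per genotype over all 5 libraries, which leaves 2 residual degrees of freedom. Benjamini-Hochberg adjusted p-values under 0.05 were called. The common biological coefficient of variation was 12.1%. The SE of a log2 fold change is its size divided by the square root of the F statistic. The comparisons were QTGAL against QTMAN knockout, and QTRT1 knockout against QTGAL, against QTMAN and against the mean of both. DESeq2 1.42.0 was an alternative. CPM values were computed here from the counts and the effective library size.

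The test was checked on simulated data for each comparison, with counts drawn for the 60966 transcripts at the fitted dispersion trend and 200 transcripts changed. It recovered 46% of 2-fold and 87% of 4-fold changes for QTGAL against QTMAN, 29% and 74% for QTRT1 against QTGAL, 27% and 72% for QTRT1 against QTMAN, and 39% and 84% for QTRT1 against both, with 4, 1, 3 and 7 calls among unchanged transcripts. Another 20 sets with no change were drawn with each transcript's own dispersion, which gives more calls without an effect than the trend does. They gave between 6 and 41 calls for QTGAL against QTMAN, with a median of 17.5, where the libraries gave 0. Both kinds of sets drew each transcript by itself, without the footprints that neighbouring rows may share.

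The rule for named transcripts was fixed before the data were examined, together with the comparisons, the tests and most of the other settings tried: an adjusted p under 0.05, at least 5 CPM in the higher group, every library of one group beyond every library of the other, and the largest absolute log2 fold change, or the smallest p where none passed. It asked for 10 per direction with a gene symbol. As no symbols could be given, it was limited afterwards to 2 identifiers per direction, 1 per 20 neighbouring rows, in the comparison of QTGAL with QTMAN knockout and that of QTRT1 with both.

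Shifts along the file order and length classes were added after the data were seen. Neighbouring transcripts with at least 100 counts over the 5 libraries were joined into runs where their counts per codon differed by less than 2-fold, and the transcript with the highest count stood for its run. Runs with at least 500 counts were used. Each library's log2 value (pseudocount 0.5, centred on the median) was set against the median of the other 4 libraries, and medians were taken over windows of 50 runs. The limit for a window was the highest absolute value in 100 orders shuffled in chunks of 10 runs. In simulated counts with a shift of -0.4 planted in 4 windows, all 4 passed the limit, at a mean of -0.405, and 0 windows did without a shift. Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3 was used. The alternatives were RLE size factors, DESeq2, no count filter, a stricter filter, a robust dispersion prior, leaving out each library, the 4 glycosyltransferase libraries alone, the replicate number as a block and, added later, leaving out the 20 most abundant transcripts, collapsed rows, 1 transcript per run, local centring and length centring.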

Results

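Ribosome-protected footprints were sequenced from 5 libraries of HEK293T, a human embryonic kidney cell line, in which 1 of 3 genes of queuosine metabolism had been knocked out. Queuosine is a modified guanosine at the wobble position of the anticodon of the tRNAs for tyrosine, histidine, asparagine and aspartate. QTRT1 is the catalytic subunit of the enzyme that inserts it, QTGAL is the glycosyltransferase that adds galactose to it in the tRNA for tyrosine, and QTMAN is the one that adds mannose in the tRNA for aspartate. There was 1 library of QTRT1 knockout cells, with 2 of QTGAL knockout and 2 of QTMAN knockout cells. Libraries of unmodified cells were not analysed here, so each comparison is between knockouts. The question the series' title raises is how the sugars on queuosine bear on translation. These data hold footprints per transcript, and no RNA levels were analysed here. A difference in footprints may thus lie in the amount of mRNA or in its translation, and the 2 cannot be told apart.

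The deposited tables listed 182398 transcripts, of which 93916 carried a length, read here as coding length in codons, and 79348 of these had a footprint in at least 1 library. Counts summed to 13918194 in the QTRT1 knockout library, to 23470931 and 12002044 in QTGAL knockout replicates 1 and 2, and to 18861713 and 25291912 in QTMAN knockout replicates 1 and 2. These sums may exceed the number of footprints, as 8561 pairs of adjacent rows held the same counts and a footprint shared by isoforms may have been counted for each. The highest 1% of transcripts, 939 rows, held between 33.6% and 35.9% of the counts of a library. The tables name transcripts by identifiers that they do not pair with gene symbols, so the footprint levels of the QTRT1, QTGAL and QTMAN genes themselves were not checked, and no gene group can be named. Transcripts are given by identifier and coding length, at most 2 in each direction for a comparison.

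Libraries of one glycosyltransferase knockout were about as alike as libraries of the 2 different ones. Across 60966 tested transcripts, the 2 QTGAL knockout libraries correlated at r = 0.973 and the 2 QTMAN knockout libraries at r = 0.979 on the log2 scale. The 4 pairs of a QTGAL with a QTMAN library correlated at between r = 0.966 and r = 0.979. The QTRT1 library correlated with the others at between r = 0.965 and r = 0.971. Its median absolute log2 difference from another library was 0.26 to 0.29, against 0.24 between the QTGAL libraries and 0.21 between the QTMAN libraries. The pair of QTGAL replicate 2 with QTMAN replicate 1 lay within that range, at r = 0.966 and 0.28. These correlations are across transcripts, which are not independent replicates.

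Footprint levels also moved together along stretches of neighbouring rows. The tables were reduced to 5740 runs of neighbouring rows with like footprint density and these were read in 114 windows, mostly of 50 runs. In the QTRT1 library, 150 consecutive runs between rows 144907 and 150279 lay lower than in the other 4 libraries by a median log2 deviation of -0.44, a ratio of 0.739, and 97.3% of the runs lay on the lower side. The last 140 runs of the file, from row 178233, lay at a median of -0.38 in QTMAN replicate 2, with 96.4% of runs lower. In the QTRT1 library 50 runs between rows 157090 and 159053 lay higher, at 0.40. Between rows 152162 and 155293 both QTGAL libraries lay lower, at -0.23 and -0.08 in replicates 1 and 2. Both QTMAN libraries lay higher, at 0.25 and 0.18 in replicates 1 and 2. The QTRT1 library, at -0.10, lay between the 2 QTGAL values. These rows were picked for their shift, so whether genotype orders the libraries there was not tested. In the next window, rows 155298 to 157079, the values were -0.27 and -0.15 in the QTGAL replicates, 0.11 and 0.21 in the QTMAN replicates and 0.17 in the QTRT1 library. Over the 5 libraries, 16 windows passed the highest value of 100 shuffled orders, and each library had between 2 and 5 of them.

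**Figure D1:**
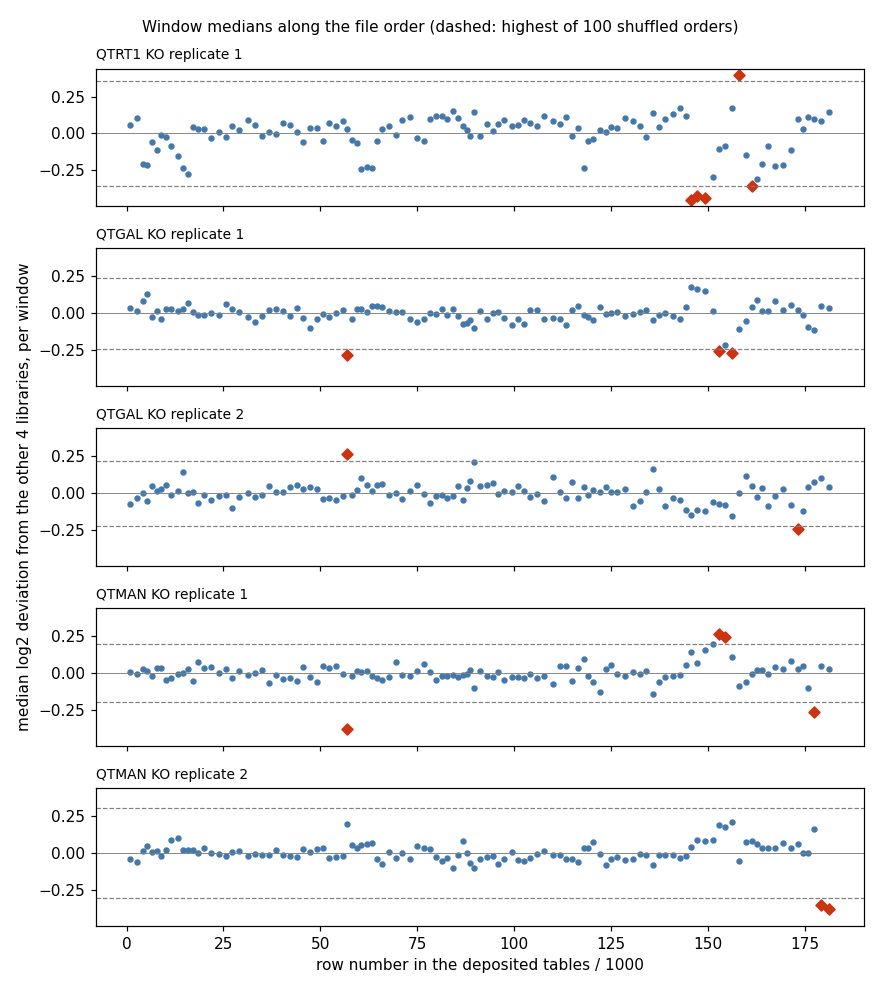
Median log2 deviation of each library from the other 4 libraries (y axis) in 114 windows of neighbouring runs along the row order of the deposited tables (x axis, row number divided by 1000). Diamonds mark the 16 windows beyond the highest absolute value of 100 shuffled orders (dashed lines), among them 3 adjacent windows in the QTRT1 library from row 144907 on, at medians of -0.45, -0.43 and -0.44, and the last 2 windows in QTMAN replicate 2.

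QTGAL knockout was compared with QTMAN knockout to ask whether knockout of the galactose and of the mannose enzyme left different footprint levels. No transcript was called different between them. The transcripts closest to the threshold were uc002uqk.4, of 1500 codons, and uc060lka.1, of 164 codons. The first stood at 2.29 ± 1.64 CPM (counts scaled to library size) in QTGAL knockout and 9.67 ± 0.184 CPM in QTMAN knockout (SD, n = 2 each), a log2 fold change of -2.24 ± 0.34 (SE) with an edgeR adjusted p of 0.323. The log2 fold change was -1.48 without QTGAL replicate 1 and -3.09 without QTGAL replicate 2. The second stood at 411 ± 19.2 against 649 ± 59.9 CPM (SD, n = 2 each), a log2 fold change of -0.66 ± 0.10 (SE) with the same adjusted p, and was called by DESeq2 (adjusted p = 0.00101). It lies in the window from row 155298 on given above, and after local centring along the file order its log2 fold change was -0.29. In the other direction, uc057mdb.1, of 199 codons, stood at 10.7 ± 1.64 against 4.62 ± 1.05 CPM (SD, n = 2 each), a log2 fold change of 1.19 ± 0.20 (SE, edgeR adjusted p = 0.382). The transcript uc057vsm.1, of 497 codons, stood at 20.5 ± 1.78 against 11.4 ± 2.56 CPM (SD, n = 2 each), a log2 fold change of 0.86 ± 0.17 (SE, edgeR adjusted p = 0.568). Without QTMAN replicate 1, the log2 fold changes of uc002uqk.4, uc060lka.1, uc057mdb.1 and uc057vsm.1 were -2.20, -0.74, 0.99 and 1.11. Without QTMAN replicate 2 they were -2.26, -0.57, 1.44 and 0.63. A fit without 1 of these libraries leaves 1 residual degree of freedom and a lone library, so its p-values are not given for these transcripts.

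Over all 60966 tested transcripts, the median absolute log2 fold change between QTGAL and QTMAN knockout was 0.17 and the median SE was 0.24. The edgeR quasi-likelihood test gave 0 calls at an adjusted p threshold of 0.05, with 3953 transcripts under an unadjusted p of 0.05 where 3048 would be expected by chance. DESeq2 gave an adjusted p for 4231 transcripts only. Of these it called 12, all lower in QTGAL knockout and all within 1 run of neighbouring rows. In counts simulated from these libraries, the edgeR test recovered 46% of transcripts changed 2-fold and 87% of those changed 4-fold in this comparison, so part of the 2-fold changes would have been missed. Smaller changes were not simulated. Simulated sets with no change gave between 6 and 41 calls, so the 0 observed lie below all 20 of them. These sets with no change were drawn with each transcript's own dispersion, and their spread thus does not match these libraries. The shares recovered come from other sets, drawn at the dispersion trend. Their spread was not checked in this way, and the shares hold for that simulation only. Between 0 and 506 transcripts were called when 1 library was left out, the highest without QTMAN replicate 2. The counts were 9 without QTGAL replicate 1, 66 without QTGAL replicate 2 and 71 without QTMAN replicate 1.

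Knockout of QTRT1, whose enzyme inserts queuosine, was compared with the mean of the QTGAL and QTMAN knockouts, each of which targets the enzyme for 1 of its 2 sugars. In the QTRT1 library 74 transcripts were higher and 24 lower, in 24 and 7 groups of neighbouring rows, with a median absolute log2 fold change of 1.33 among the calls. The transcript uc003xqp.5, of 269 codons, fell to 0.498 CPM (7 counts) from 5.48 ± 1.92 CPM in QTGAL knockout and 8.37 ± 1.81 CPM in QTMAN knockout (SD, n = 2 each). Its log2 fold change was -3.77 ± 0.48 (SE, edgeR adjusted p = 0.0151), with an adjusted p of 0.0541 among transcripts of at least 5 CPM in 2 libraries and of 0.0696 with 1 transcript per run. The transcript uc002mpr.4, of 404 codons, fell to 1.28 CPM from 10.6 ± 3.33 and 10.3 ± 0.450 CPM (SD, n = 2 each), a log2 fold change of -3.04 ± 0.35 (SE, edgeR adjusted p = 0.00779). Whether this or another lower transcript is that of the QTRT1 gene itself could not be checked, so a fall here may be the knockout and not an effect of it. The transcript uc032hlq.2, of 1347 codons, rose to 5.06 CPM from 0.821 ± 0.627 and 0.607 ± 0.105 CPM (SD, n = 2 each), a log2 fold change of 2.94 ± 0.40 (SE, edgeR adjusted p = 0.0245, and 0.0696 with 1 transcript per run). The transcript uc002ohs.3, of 196 codons, rose to 7.33 CPM from 1.64 ± 0.530 and 1.07 ± 0.120 CPM (SD, n = 2 each), a log2 fold change of 2.44 ± 0.28 (SE, edgeR adjusted p = 0.00779).

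**Figure D2:**
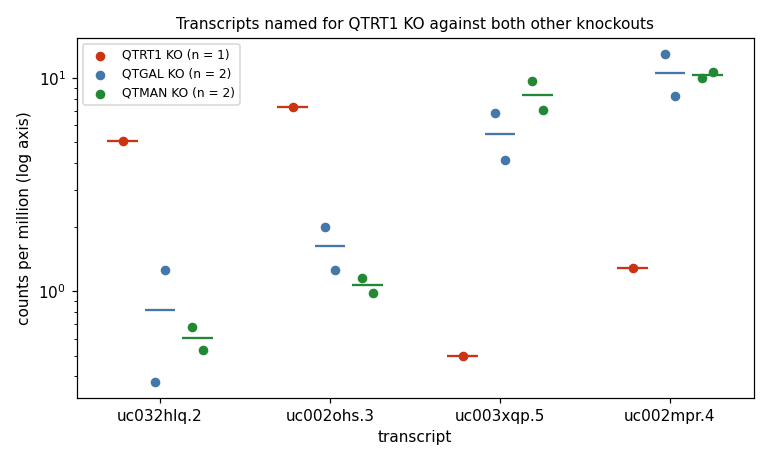
Footprint level in CPM (y axis, log scale) of the 4 transcripts named for the comparison of QTRT1 knockout with both other knockouts, per library (points) with the mean of each genotype (lines). The QTRT1 library lies above all 4 other libraries for uc032hlq.2 and uc002ohs.3 and below all of them for uc003xqp.5 and uc002mpr.4.

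The called transcripts had a median coding length of 468.5 codons where they were higher and 637 where they were lower, against 251 codons over all tested transcripts. Their median level was 8.26 CPM, against 3.78 CPM over all tested transcripts. The rows uc003xqp.5, uc002mpr.4, uc032hlq.2 and uc002ohs.3 lie in windows whose own medians in the QTRT1 library were -0.031, -0.311, -0.358 and -0.224. These p-values rest on 1 QTRT1 library, which was assumed to vary like the libraries of the other genotypes, and on libraries that no label places in separate cultures. In 20 simulated sets with no change and each transcript's own dispersion, the same test called between 4 and 35 transcripts. These sets drew each transcript by itself, while the 98 observed calls lie in 31 groups of neighbouring rows, so the 2 counts are not on one footing and an excess over no change is not shown by them. The number called depended on the filter, with 9 among transcripts of at least 5 CPM in 2 libraries and 1161 with no filter. The first of these filters tested only 67 of the 98 calls, so the fall mixes calls not tested with calls lost. It leaves out any transcript that reaches 5 CPM in the QTRT1 library alone. The filter of at least 5 CPM in 2 libraries left out uc032hlq.2 and uc002ohs.3. DESeq2 called 69 higher and 98 lower among the 20778 transcripts for which it gave an adjusted p. Of the named transcripts above, only uc002mpr.4 was among these. The edgeR count was 47 after local centring, 38 higher and 9 lower, and 4 when 1 transcript was kept per run. It rose to 478 without QTGAL replicate 2, to 428 without QTMAN replicate 1 and to 1438 without QTMAN replicate 2.

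Set against QTMAN knockout alone, 43 transcripts were higher and 28 lower in the QTRT1 library, with a median absolute log2 fold change of 1.83. Among them, uc003xqp.5 was lower by 16.5-fold and uc002mpr.4 by 8.03-fold (edgeR adjusted p = 0.0131 for both). The transcripts uc002ohs.3 and uc032hlq.2 were higher by 6.87-fold and 8.34-fold (edgeR adjusted p = 0.0131 and 0.0416, the latter 0.0871 with 1 transcript per run). Simulated sets with no change, each transcript drawn by itself, gave between 4 and 40 calls, and the 71 calls here lie in 23 groups of neighbouring rows. After local centring 36 transcripts were higher and 13 lower. DESeq2 called 45 higher and 75 lower among the 34962 transcripts for which it gave an adjusted p. With the filter of at least 5 CPM in 2 libraries, edgeR called 13 higher and 13 lower, and only 45 of the 71 calls were tested. The edgeR count rose to 172, 342, 246 and 1144 without QTGAL replicate 1, QTGAL replicate 2, QTMAN replicate 1 and QTMAN replicate 2.

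Set against QTGAL knockout alone, 5 transcripts were higher and 1 lower in the QTRT1 library, in 2 and 1 groups of neighbouring rows. The lower one was uc002mpr.4, which fell by 3.07 ± 0.36 on the log2 scale (SE, edgeR adjusted p = 0.0277), an 8.42-fold difference, and which may be the targeted gene itself, as said above. It was not called among transcripts of at least 5 CPM in 2 libraries (edgeR adjusted p = 0.0509) or with 1 transcript per run (edgeR adjusted p = 0.0835). The other 3 named transcripts had the same direction as above and edgeR adjusted p-values of 0.135 for uc032hlq.2, 0.0895 for uc002ohs.3 and 0.0777 for uc003xqp.5. With all libraries the log2 fold changes of uc032hlq.2, uc002ohs.3 and uc003xqp.5 were 2.82, 2.10 and -3.49. They were 1.99, 2.53 and -3.03 without QTGAL replicate 1, and 3.73, 1.87 and -3.75 without QTGAL replicate 2. The p-values of fits without a library are not given for these transcripts, as such fits leave 1 residual degree of freedom. Simulated sets with no change, each transcript drawn by itself, gave between 3 and 33 calls. Their spread does not match these libraries, as said for QTGAL against QTMAN. They therefore do not tell whether the calls here exceed no change. Under an unadjusted p of 0.05 there were 6114 transcripts where 3048 would be expected by chance, and the simulated sets held a mean of 4.97% of the 60966 tested. Among the 5 higher transcripts was uc031rsb.2, of 1691 codons, which the naming rule did not pick. It stood at 73.1 CPM in the QTRT1 library, 23.3 and 26.4 CPM in the QTGAL replicates and 18.1 and 19.0 CPM in the QTMAN replicates. Its edgeR adjusted p was 0.00444 here and 0.000215 against both, again from 1 QTRT1 library. With at least 5 CPM in 2 libraries, edgeR called 4 transcripts, all higher and in 1 group of neighbouring rows. DESeq2 called 30 higher and 33 lower among the 13687 transcripts for which it gave an adjusted p. The edgeR count rose to 227 without QTGAL replicate 2, to 342 without QTMAN replicate 1 and to 869 without QTMAN replicate 2.

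All 6 transcripts called against QTGAL knockout were also called against QTMAN knockout in the same direction. Independent lists of these sizes would share 0.00353 higher and 0.000459 lower transcripts. These 2 values take each row as independent, while the 6 calls lie in 3 groups of neighbouring rows, so they understate the overlap to be had by chance. Both comparisons use the same QTRT1 library, and simulated sets with no change shared up to 12 calls. As the simulated spread does not match these libraries, that number does not settle whether the overlap exceeds no change. The log2 fold changes of the 2 comparisons correlated at r = 0.781 across transcripts, against a mean of 0.739 in the simulated sets, and their covariance was 0.266 against 0.155. The shared library cannot be split, so part of the overlap may come from it. Whether the QTRT1 library differed more from one glycosyltransferase knockout than from the other is the comparison of QTGAL with QTMAN knockout above.

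Transcript groups by coding length differed little. Transcripts of over 1000 codons (1043 runs) lay above those of up to 100 codons (239 runs) by 0.061 on the log2 scale in the QTRT1 library, relative to the mean of the 5 libraries. The same difference was -0.031 and -0.011 in the QTGAL replicates and -0.058 and 0.043 in the QTMAN replicates. The group means of QTGAL and QTMAN knockout differed by -0.014, less than the 0.101 between the 2 QTMAN libraries. With 2 libraries against 2, an exact permutation test cannot give a two-sided p below 0.333.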

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

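The number of calls depended on the processing, and the cause was not tested except where stated. In the order of the comparisons below, DESeq2 gave an adjusted p for 4231, 13687, 34962 and 20778 transcripts, where edgeR tested 60966. Its counts are thus over fewer transcripts than those of edgeR. For QTGAL against QTMAN knockout (0 calls), DESeq2 gave 12, no count filter 282, and leaving out 1 library 0 to 506; 0 calls remained with RLE factors, the stricter filter, the robust prior, the 4 libraries alone and the 5 alternatives added after seeing the data. The replicate number as a replicate block also gave 0 calls, with 5459 unadjusted p-values under 0.05 against 3890 in the 4 libraries alone without it. The 0 calls were a near miss on 1 residual degree of freedom. The edgeR adjusted p with the block was 0.0534 for uc057mdb.1, uc002uqk.4 and uc060lka.1, and 0.0786 for uc057vsm.1. Without the block, in the 4 libraries alone, these values were 0.367 to 0.566. Deviations of equal numbers correlated at 0.174 over the only 2 pairs, and nothing in the labels pairs them. For QTRT1 against QTGAL (6 calls), RLE gave 11, DESeq2 63, no filter 645, the stricter filter 4 (0 lower), the robust prior 69, collapsed rows 19, length centring 12, 1 transcript per run 2, and leaving out 1 library 7 to 869. For QTRT1 against QTMAN (71 calls), DESeq2 gave 120, no filter 1159, the stricter filter 26, the robust prior 287, collapsed rows 107, 1 transcript per run 8, and leaving out 1 library 172 to 1144. For QTRT1 against both (98 calls), DESeq2 gave 167 (69 higher, 98 lower), no filter 1161, the stricter filter 9, the robust prior 289, 1 transcript per run 4 of the 26 calls it tested, local centring 47, and leaving out 1 library 95 to 1438. Leaving out a QTGAL or QTMAN library leaves 1 residual degree of freedom and a lone library assumed to vary like the others. The stricter filter tested only 45 of the 71 calls against QTMAN and 67 of the 98 against both. The planned gene list, codon content and protein-coding alternatives were not run, as no gene names were given. The 8 named transcripts kept their direction in all alternatives that tested them. The naming rule asked every library of one group to lie beyond every library of the other. A kept direction was thus largely fixed by that choice and is no separate support. In the comparison each was named for, calls were the same in 97 of these, gained in 12 and lost in 3; for the 4 named in QTRT1 against both, they were the same in 29, gained in 18 and lost in 2 against QTGAL alone, and the same in 50 and lost in 1 against QTMAN alone.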

Other observations

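All tests here were added after the data were seen. The tests of shared footprints between isoforms, of the windows outside rows 56522 to 57420, of the length trend, and of 1 library against 3 were chosen only after the result was seen; those of length centring, of all windows together, of 1 library against 4 and of local centring were set down after the pattern was seen but before their own values were.

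A surprising feature of these tables is that footprint levels shift mostly the same way over stretches of neighbouring transcripts, mostly in 1 or a few libraries. The size of the shift varied between runs, with quartiles of -0.57 and -0.27 in the QTRT1 stretch of 150 runs. The QTRT1 library held 3 adjacent windows at medians of -0.45, -0.43 and -0.44, where 96% to 100% of runs moved the same way. QTMAN replicate 2 held the final 2 windows of the file at -0.36 and -0.39, while QTMAN replicate 1 did not pass the limit there. Rows 152162 to 157079, with 4 of the 16 windows past the limit, are an exception: in all 3 windows there both QTGAL libraries lay lower and both QTMAN libraries higher, and the QTRT1 library went from -0.11 in the first to 0.17 in the last. Whether genotype orders them was not tested, as they were picked for their shift. Isoforms that share footprints argue for short-range likeness only, and in the QTRT1 library runs 50 places apart still correlated at 0.133, above the highest of 100 shuffled orders at 0.035. A coding length trend is argued against as well, since 15 of the 16 windows stayed past the limit after centring by length. A gained or lost chromosome segment in the cells of single knockout populations as the one cause of all windows is argued against by 1 window only, treated next. That argument is weak, as it rests on a value near 0. For the other windows a segment is a candidate explanation that was not tested. There 94.2% of runs lay on the side of their window. But windows were picked by their median, and the highest window of a shuffled order already had a mean of 71.5%. No DNA was measured, the row order was not checked against a genome, and a broad change in chromatin or transcription would give the same values, so the hypothesis stays open.

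One window stands apart from that pattern. Between rows 56522 and 57420, levels were lower in QTGAL replicate 1 (-0.28) and QTMAN replicate 1 (-0.38) and higher in QTGAL replicate 2 (0.27) and QTMAN replicate 2 (0.20, not past the limit). Its runs were the shortest of all 114 windows, with a median of 137 codons against 471 over all runs. Its mean count was 283% of that of all runs, the highest of the windows. In QTMAN replicate 1 the runs below and above the median abundance lay at 0.038 and -0.44. A gained or lost segment does not give opposite ways, but 0.038 is near 0, so this is a weak argument. In QTGAL replicates 1 and 2 both parts moved the same way, at -0.11 and -0.37 and at 0.11 and 0.38. The 2 libraries of each glycosyltransferase knockout differed here. The values follow the replicate number, which was set here in accession order, and nothing in the labels pairs libraries of equal number. The QTRT1 library stood at 0.03.

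The calls of the QTRT1 library rest on 1 library, so genotype and library cannot be separated by design. Set alone against the other 4 libraries, the QTRT1 library gave 83 calls, and the others gave 33, 0, 30 and 16 (QTGAL replicates 1 and 2, QTMAN replicates 1 and 2). The highest, 33, met the bound set before that value was seen against single libraries, under 1 in 2 of the QTRT1 count, but that bound was wrong: the rest then holds the QTRT1 library, which widens their spread, and only 2.37% to 4.87% of unadjusted p-values lay under 0.05. With 3 glycosyltransferase libraries as the rest, the other libraries gave 55, 0, 38 and 19 calls and the QTRT1 library between 27 and 91, depending on which 3 were used. The 55 of QTGAL replicate 1 exceeds 2 of these 4 counts, so a deviation of single libraries is a candidate explanation for the number of calls. The share of unadjusted p-values under 0.05 was 8.89% to 12.3% for the QTRT1 library and 2.88% to 6.77% for the others. The 4 QTRT1 values reuse 1 library, so they are not replicates and their range measures no spread between libraries. The calls of QTGAL replicate 1 were all lower and those of QTMAN replicate 1 all higher. Those of QTMAN replicate 2 and of the QTRT1 library went both ways. The numbers of calls are of rows and not of groups of neighbouring rows. Shifted stretches may account for part: 45.9% of the 98 calls stayed after local centring. The 53 lost calls fell only from a median absolute log2 fold change of 1.15 to 1.02, while their median SE went from 0.185 to 0.202 and their median adjusted p from 0.0409 to 0.0873, and 8 of them lay in windows of the QTRT1 library past the limit. These 8 were lower in the QTRT1 library, with log2 fold changes of -0.80 to -0.92. Their window's own median there was -0.44, so the stretch can account for part of these falls. Of the 98 calls, 9.18% lay in such windows, against 4.87% of the tested transcripts. Most lost calls were near the threshold before. How far stretches account for those outside such windows cannot be told apart from that.

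Between QTGAL and QTMAN knockout, no difference in the coding length trend was seen beyond that between libraries of the same genotype. With 2 libraries of each, a small difference by genotype could not have been shown. The 2 QTMAN libraries differed by 0.101 in the trend, more than the means of QTGAL and QTMAN knockout did (-0.014). The QTRT1 library had the highest trend of the 5, at 0.061, and with 1 library of its genotype it was not tested.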
